A study of Mus musculus with 8 samples.

How the data were processed

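Total RNA of mature 3T3-L1 adipocytes from 4 groups (saline, chrysotile, crocidolite and amosite; 2 arrays each, 8 in all) was labelled with Cy3 and hybridised to Agilent mouse gene expression arrays. Per the file headers the arrays were scanned on 1 slide and on 1 date and read with Feature Extraction 10.7.1.1, and per the labels with version 10.7. The deposited values are linear intensity per spot, the processed signal, from which the authors' scanner software had subtracted background and removed spatial and multiplicative trends, with surrogate values near background and no scaling between arrays. The deposited value table has the same intensity as the scanner files, with a largest difference of 0. The labels say that arrays were run in duplicate and not whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The slide column of an array was its replicate number and its slide row its group, so row and group cannot be separated, and a block by slide or date could not be run with 1 of each.

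The log2 intensity was centred on the 75th percentile of each array. Control spots and spots with outlier flags (99 to 183 per array) were left out, spots of a probe were averaged, and 9 probes missing on an array were dropped. A probe was kept if it was well above background, by the scanner's own call, on both arrays of at least 1 group, which left 33044 probes. The brightest probe stood for each gene, giving 22915 genes, 8887 of them without a symbol, and 6642 with more than 1 probe passing. Symbols were brought up to date for 26762 probes through their transcript identifiers. All comparisons came from 1 limma fit (lmFit and eBayes, 4 residual degrees of freedom, 2.22 prior) with Benjamini-Hochberg adjusted p at 0.05, two-sided. The 3 fibres were compared with saline, with each other, and chrysotile with the mean of the amphiboles. The software was R 4.3.3 with limma 3.58.1, the data.table package (1.17.8) and statmod 1.5.0. A fold against a group under background on both arrays is given as at least N-fold, computed with that group raised to the lowest value of any probe called above background on each of its arrays. Where the group already lay above that value, the figure is the plain fold change. It carries no error range and is not a proven minimum.

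Gene lists (31, with 742 different genes, 678 of them measured and 33 in more than 1 list), the panel of 25 genes, the comparisons and the alternatives were fixed before the data were examined. The lists cover adipocyte identity, lipogenesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, thermogenic genes, insulin signalling, adipokines, inflammatory cytokines, NF-kB, acute phase, interferon, NRF2, iron, metal response, integrated stress response, ER chaperones, heat shock, p53, cell cycle, preadipocyte, macrophage, collagens, matrix proteases, TGF-beta with SRF and YAP targets, growth factors, lysosome, autophagy, hypoxia, circadian and ribosomal genes. Each was tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the data, which gave 0 calls in all 6 comparisons. That second form was run without the replicate block, and a call lost with it need not mean correlated genes. For growth factors with crocidolite the estimate was -0.0191, under the preset, yet the camera p rose from 0.000366 to 0.0163. The fry rotation test, which asks whether a list's genes move on balance 1 way, gave 1 call (growth factors with crocidolite, adjusted p = 0.046), and its mixed form, which asks whether they change in either direction, 4, 10, 0, 0, 1 and 0. Neither compares a list with other genes. The rule for named genes takes the largest changes past the threshold, and where none passes the 10 smallest p with a symbol, with the panel and up to 2 members of each list as values. Not all of these list members are printed, and 2 genes are not reported here at all.

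Same-numbered arrays deviated together, with correlations of 0.25 to 0.46 in the 6 pairs of groups, and the first principal component (32.3% of the variance) separated the replicate numbers. A fit with the number as a replicate block (3 residual degrees of freedom, 2.08 prior) is therefore given wherever it changes the call of a list or panel gene. Counts and shares given below as by chance take the arrays as exchangeable. Since same-numbered arrays deviated together, those figures are likely too high, and a value under them does not mean less than chance. The SD of the difference between replicates over genes was 0.543 for saline, 0.434 for chrysotile, 0.396 for crocidolite and 0.374 for amosite.

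The fit was tested on simulated data with changes put into chrysotile against saline and a spread drawn from the fit of all 4 groups. It called 18 of 67 genes changed by a log2 of 1, 51 of 67 at 2 and 65 of 66 at 4, with 6 false calls among 22715 unchanged genes. Of 5 lists shifted by 0.5, the preset test called 5 and the estimated one 4, and neither called an unshifted list. Genes were simulated as independent, so this does not test either method on correlated lists. All arrays were given the same spread, with the largest gene spreads capped and no effect of replicate number. Saline and chrysotile replicates differed most in the data (SD 0.543 and 0.434), so real detection in that comparison may be lower. In the data the estimated correlation reached 0.821, for oxidative phosphorylation. The alternatives were normexp background correction (offset 50), quantile normalization, a 75th percentile over bright probes only, no filter on dim probes, only probes well above background on all arrays, outlier spots kept, every probe tested, a trended and robust prior, the 2 groups alone, a 2-fold minimum, the deposited values themselves, the replicate block, and each array left out in turn, with the lone array of its group assumed to vary like the other groups. Added after seeing the data were the replicate block with a trended and robust prior, and normexp with the block. The sign of named genes with more than 1 probe differed between probes in 1 of 23 for chrysotile (Cdkn1a), 3 of 17 for crocidolite (Cdkn1a, Rpl3 and Sqstm1) and 10 of 21 for amosite.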

Results

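Gene expression was measured in mature 3T3-L1 adipocytes, fat cells differentiated in culture from a mouse preadipocyte line, after 72 h with saline or with 1 of 3 asbestos fibres. Chrysotile is a serpentine asbestos with curled fibres, and crocidolite and amosite are amphibole asbestos with straight, iron-rich fibres. The labels give 10 mg/cm2 for each fibre, a large amount whose unit could not be checked here. Each of the 4 groups had 2 arrays, and the 8 arrays lay on 1 slide. Between 31293 and 34983 of 55681 probes (56.2% to 62.8%) were well above background on an array, and the 75th percentile of the processed intensity ran from 340.1 to 453.4. The number of arrays limits the precision of every value. In each comparison 22915 genes were tested, of which 14028 have a symbol. Values are log2 fold changes ± SE (n = 2 arrays per group, spread pooled over the 8 arrays), and probe positions are on mouse build mm9. Which exon or untranslated region a probe lies in was not analysed here.

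The comparison of chrysotile with saline asks which transcripts differ in fat cells after 72 h with the serpentine fibre. Some panel transcripts of secreted inflammatory proteins were higher with chrysotile. Saa3, which encodes an acute-phase protein made by fat cells, was higher by 4.13 ± 1.01 (17.5-fold, probe on chromosome 7, 53970389 to 53970448), and Ccl2, a chemokine that attracts monocytes, by 3.01 ± 0.57 (8.05-fold, chromosome 11, 81850650 to 81850709). Spp1, which encodes osteopontin, was higher by 2.42 ± 0.32 (chromosome 5, 104868502 to 104868561), and Lcn2, which encodes an iron-siderophore-binding lipocalin, by 2.41 ± 0.63 (chromosome 2, 32240199 to 32240258). Fasn, the fatty acid synthase, stood at -0.46 ± 0.13 (chromosome 11, 120667666 to 120667725). These 5 were among the 6 of 25 panel genes that passed 0.05 adjusted over the list alone, with adjusted p from 0.0058 for Spp1 to 0.042 for Fasn, and in each both replicate pairs had the same sign. None passed over all genes tested. The 2 chrysotile arrays differed widely for Saa3, so its fold change is imprecise. With the replicate block, Lcn2 no longer passed (adjusted p = 0.059), and Hmox1, the heme-degrading enzyme, passed with 1.32 (0.0031 adjusted over the list alone, against 0.61 without the block). The main adipocyte markers did not pass and lay close to 0: Adipoq -0.19, Lep -0.15, Retn -0.22, Cfd -0.11, Pparg -0.03, Cebpa -0.14, Fabp4 0.00, Plin1 -0.21, Slc2a4 -0.32 and Scd1 0.02. The other panel values were 0.59 for Il6, 0.23 for Nqo1, 0.14 for Mt1, -0.68 for Tfrc, 0.20 for Cdkn1a, 0.31 for Ddit3, 0.55 for Hgf and 0.04 for Vegfa. The 6 panel calls fell to 0 without saline replicate 1 and to 2 (Ccl2 and Spp1) without saline replicate 2 or any 1 crocidolite or amosite array. They numbered 4 without chrysotile replicate 2, and without chrysotile replicate 1 they numbered 6, with Hgf in place of Fasn.

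Over all genes, limma called 0 of 22915 for chrysotile against saline (smallest adjusted p = 0.12), and 1259 had an unadjusted p under 0.05 (647 higher, 612 lower), where chance gives 1146. The count was also 0 with the replicate block (2416 unadjusted), with a trended and robust prior (1279, smallest adjusted p = 0.0502) and with the 2 groups fitted alone (705). With quantile normalization it was 3, Tnnt2, Vmn2r109 and 1 transcript without a symbol (smallest adjusted p = 0.00503). Chosen after seeing the data, the block with a trended and robust prior called 6 and normexp with the block 2. The 10 smallest p belonged to Tnnt2, Vmn2r109, Ereg, Vmn1r176, Ptgs2, Hmga2, Spp1, Plaur, Efhb and Tinagl1. Tnnt2, which encodes a troponin of the heart muscle thin filament, was higher by 2.79 ± 0.21 (6.93-fold, chromosome 1, 137747976 to 137748288), and Hmga2, an architectural chromatin protein of growing cells, by 2.37 ± 0.31 (5.16-fold, chromosome 10, 119798739 to 119798798). Ereg, an epidermal growth factor receptor ligand, stood at 1.72 ± 0.20 and Plaur, the urokinase receptor, at 1.48 ± 0.20, each above background on 1 of 2 saline arrays. Ptgs2, the inducible prostaglandin synthase, was at least 1.02-fold higher and Efhb at least 1.57-fold higher, both under background in saline. The receptor genes Vmn2r109 and Vmn1r176 were at least 2.15-fold and 1.38-fold lower, both under background with chrysotile and Vmn1r176 above it on 1 of 2 saline arrays. Tinagl1 stood at 0.77 ± 0.12. At a 2-fold change with no overlap between the arrays, 185 genes were higher and 108 lower, and 29.6% of all genes had no overlap, where chance gives 33.3%. Without saline replicate 2 the calls numbered 65, without chrysotile replicate 1 they numbered 7 and without chrysotile replicate 2 there was 1.

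**Figure D1:**
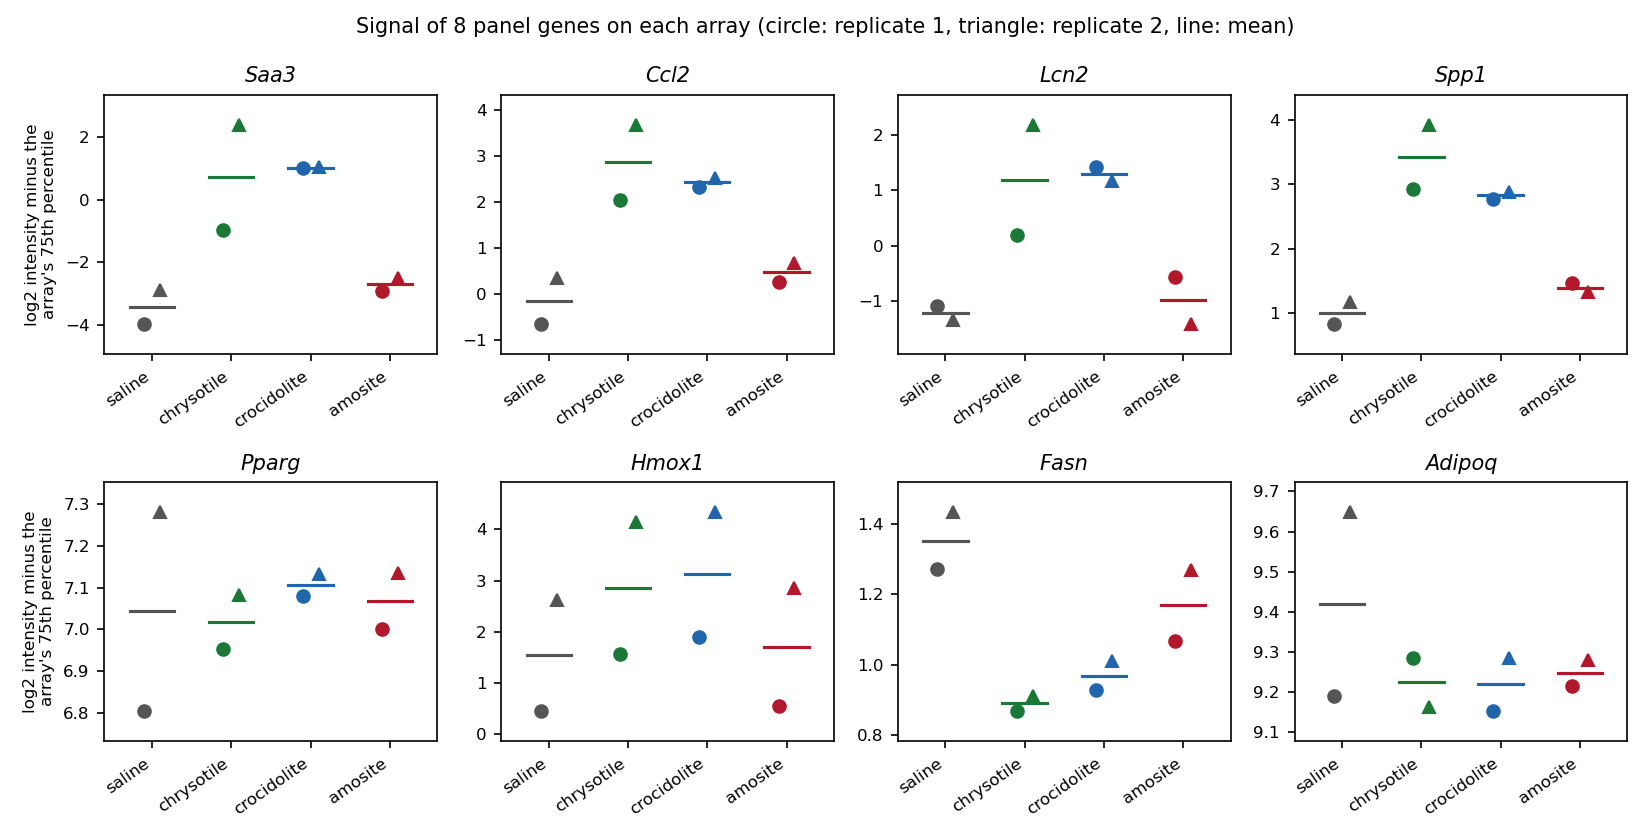
Log2 processed intensity relative to each array's 75th percentile, for 8 panel genes on each of the 8 arrays, with points for replicates and bars for the mean of each group. Saa3, Ccl2, Spp1 and Lcn2 lie higher with chrysotile and crocidolite than with saline, and their amosite differences are between 0.23 and 0.71.

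Among the gene lists, the cytokine, adhesion, matrix protease and contractile groups rose with chrysotile. The 23 inflammatory cytokines and chemokines had a median of 0.66 with 19 positive (camera adjusted p = 6.48e-10, adjusted p = 0.22 with an estimated correlation). The matrix proteases and their inhibitors had a median of 0.42 with 20 of 23 positive (adjusted p = 6.48e-10, 0.22 with an estimated correlation). The targets of TGF-beta, SRF and YAP, contractile and matrix-signalling genes, had a median of 0.41 with 24 of 24 positive (adjusted p = 1.98e-07, 0.22 with an estimated correlation). NF-kB feedback and adhesion genes had a median of 0.26 (adjusted p = 1.71e-06, 0.22 with an estimated correlation), and hypoxia and glycolysis genes 0.21 (adjusted p = 1.71e-06, 0.22 with an estimated correlation). The adipokines rose, with a median of 0.23 (adjusted p = 3.4e-05, 0.30 with an estimated correlation), but the 5 members that passed adjusted over the list alone included Saa3, Ccl2, Spp1 and Lcn2, which act in inflammation and the matrix. Acute phase and complement genes had a median of 0.49 (adjusted p = 0.000177, 0.41 with an estimated correlation), and growth factors 0.14 (adjusted p = 0.0136, 0.22 with an estimated correlation). These 6 calls, for the inflammatory, matrix protease, TGF-beta, NF-kB, hypoxia and adipokine lists, held in all 15 other settings of the preset test. In every comparison some of the 15 are weak checks. The deposited values equal those of the main fit, so that setting could not differ. Leaving out an array of a group not compared changes the spread but not the fold changes. The acute phase call ended without saline replicate 1 (adjusted p = 0.0673) and chrysotile replicate 2 (0.0847), and that of the growth factors without saline replicate 2 (0.311).

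Members of these lists passed adjusted over the list alone, and those named next, beyond the panel, were chosen after their values were seen. The inflammatory list had 6 of 23 higher: Ccl2, Ccl7 (1.35 ± 0.25), Ccl8 (2.28 ± 0.42, 4.87-fold), Cx3cl1 (0.66 ± 0.19), Csf1 (0.75 ± 0.17), a macrophage growth factor, and Ptgs2. The matrix list had 7 of 23 higher, among them Plau, the urokinase (at least 2.81-fold, under background in saline), the stromelysin Mmp3 (1.65 ± 0.39), the collagenase Mmp13 (1.83 ± 0.42), Mmp10 (at least 1.65-fold, under background in saline) and the protease inhibitor Timp1 (1.07 ± 0.28). In the NF-kB list Tlr2 (1.12 ± 0.28), Nfkbie (0.97 ± 0.22), Vcam1 (0.71 ± 0.14) and Nfkbiz (0.61 ± 0.15) passed, and in the acute phase list Saa3, Lcn2, the serpin Serpina3g (2.57 ± 0.57) and the complement factor C4b (1.98 ± 0.52). The TGF-beta list had 0 of 24 past the threshold, and 10 of 24 with the replicate block. Its largest value was 1.42 ± 0.92 for Ccn2. Ereg was the 1 growth factor of 26 to pass, with Hbegf at 0.99 ± 0.27, and Plk2, a polo-like kinase (0.99 ± 0.17), the 1 p53 target of 21. In the hypoxia list Car9 stood at 1.30 ± 0.59 and Ndrg1 at 0.73 ± 0.19, and 0 of 28 passed.

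Metabolic lists fell with chrysotile by the preset test. Oxidative phosphorylation had a median of -0.19 with 30 of 30 negative (adjusted p = 7.71e-07, 0.54 with an estimated correlation), with Cycs at -0.45 ± 0.13 and Sdhb at -0.40 ± 0.19, but its medians in the replicate pairs were 0.09 and -0.53. Adipocyte identity stood at -0.16 (adjusted p = 0.00365, 0.57 with an estimated correlation), with the carbonic anhydrase Car3 at -0.85 ± 0.66 and the receptor Adrb3 at -0.46 ± 0.76. Fatty acid oxidation stood at -0.15 (adjusted p = 0.00647, 0.54 with an estimated correlation), with pair medians of 0.08 and -0.36. Lipogenesis stood at -0.13 (0.0147, 0.54 with an estimated correlation), thermogenic genes at -0.37 (0.0152, 0.30 with an estimated correlation) and insulin signalling at -0.05 (0.0483, 0.57 with an estimated correlation). Values of their members included -1.02 ± 0.36 for Thrsp, a lipogenic regulator, -0.49 ± 0.18 for Acacb, -0.81 ± 0.27 for Cidea, a lipid droplet protein, -0.46 ± 0.27 for Ppargc1a, -0.44 ± 0.55 for Acads, -0.48 ± 0.26 for Tbc1d4 and -0.42 ± 0.29 for Irs1. No member of these 6 lists passed adjusted over the list alone. The insulin signalling median lay at percentile 7.35 of 10000 random lists of genes of like brightness. All 6 calls ended without saline replicate 2, with adjusted p from 0.454 to 0.831, and the mean of the adipocyte identity list was then 0.06. Without chrysotile replicate 1 those of adipocyte identity, lipogenesis, thermogenic genes and insulin signalling ended (0.105 to 0.941), without chrysotile replicate 2 that of fatty acid oxidation (0.11), and insulin signalling also without saline replicate 1 (0.0574) or a crocidolite array (0.0511). With no filter on dim probes all but that of oxidative phosphorylation ended (0.0707 to 0.332). With normexp background correction those of lipogenesis, fatty acid oxidation and insulin signalling ended (0.0786 to 0.324), and with only probes bright on all arrays that of insulin signalling (0.0517).

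The interferon response list rose, with a median of 0.34 and 33 of 35 positive (adjusted p = 3.4e-05, 0.54 with an estimated correlation), and its pair medians were 0.57 and 0.10. Isg15, a ubiquitin-like interferon product, stood at 0.81 ± 0.49 and Rtp4 at 0.72 ± 0.63. Cytosolic ribosomal proteins rose by a median of 0.15 (0.000882, 0.57 with an estimated correlation, Rpl5 0.44 ± 0.19). Random lists of genes of like brightness had a median of 0.10, and the ribosomal list lay at their percentile 90.35. Lysosome and phagosome genes rose by 0.16 (0.000487, 0.30 with an estimated correlation, Scarb2 0.55 ± 0.19, Lgmn 0.44 ± 0.15) and ER chaperones by 0.11 (0.00641, 0.30 with an estimated correlation, Calr 0.42 ± 0.16, Hspa5 0.40 ± 0.16). Cell cycle genes rose by 0.10 (0.00641, 0.54 with an estimated correlation, Cdc6 0.74 ± 0.21, Ube2c -0.41 ± 0.26, pair medians 0.30 and -0.05), and integrated stress response genes by 0.15 (0.0147, 0.54 with an estimated correlation, Atf3 0.76 ± 1.05, Gdf15 0.46 ± 0.56). Iron handling genes rose by 0.14 (0.0226, 0.30 with an estimated correlation, Steap1 1.33 ± 0.30) and p53 targets by 0.02 (0.0215, 0.30 with an estimated correlation). The medians of ER chaperones and p53 targets lay at percentiles 96.94 and 70.73 of random lists of like brightness. Lists not called had medians of -0.03 for cholesterol synthesis (Srebf2 -0.58 ± 1.24), 0.07 for NRF2 antioxidant genes (Tkt 0.87 ± 1.30), 0.09 for the metal response (Mt2 0.89 ± 0.26), 0.08 for heat shock (Hspb1 at least 1.66-fold higher, under background in saline). The others were 0.01 for preadipocyte and fibroblast genes (S100a4 1.25 ± 0.41, Klf2 1.14 ± 0.39), -0.02 for collagens and matrix (Col12a1 1.15 ± 0.33, Eln -0.63 ± 0.67). They were 0.03 for autophagy (Gabarapl2 0.58 ± 0.40, Sqstm1 0.32 ± 0.14) and -0.11 for the circadian clock (Hlf -0.75 ± 0.17, Ciart 0.51 ± 0.23). The macrophage markers had a median of 0.16 (adjusted p = 0.102, 0.0269 with the replicate block), with Mpeg1 at 0.96 ± 0.82 and Cd14 at 0.70 ± 0.30. The interferon, ER chaperone and lysosome calls ended without saline replicate 1 (adjusted p 0.0666 to 0.491) or chrysotile replicate 2 (0.0872 to 0.245), and the interferon mean was -0.09 without saline replicate 1. The cell cycle call ended without saline replicate 1 (0.31) or chrysotile replicate 1 (0.25), those of the integrated stress response and p53 targets without saline replicate 2 (0.409 to 0.579) or chrysotile replicate 1 (0.208 to 0.405). The iron call ended without saline replicate 2 (0.409) or chrysotile replicate 2 (0.256), and the ribosomal call without chrysotile replicate 1 (0.489). With quantile normalization the stress response and ribosomal calls ended too (0.0683 and 0.168).

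Crocidolite was compared with saline to ask the same of an amphibole fibre. Here too some panel transcripts of secreted inflammatory proteins were higher: Saa3 by 4.44 ± 1.01 (21.7-fold), Ccl2 by 2.57 ± 0.57 (5.95-fold), Lcn2 by 2.52 ± 0.63 (5.73-fold) and Spp1 by 1.82 ± 0.32 (3.54-fold). These 4 were among the 5 of 25 panel genes that passed adjusted over the list alone (adjusted p 0.018 to 0.033), with both replicate pairs positive in each, and none passed over all genes tested. With the replicate block 10 passed, adding Fasn (-0.38, adjusted p = 0.031), Hmox1 (1.58, 0.0013), the transferrin receptor Tfrc (-0.88, 0.037), the stress-induced transcription factor Ddit3 (0.36, 0.037) and the growth factor Hgf (0.73, 0.043). The adipocyte markers did not pass: Adipoq -0.20, Lep -0.22, Retn -0.31, Cfd -0.23, Pparg 0.06, Cebpa -0.11, Fabp4 -0.03, Plin1 -0.14, Slc2a4 -0.29 and Scd1 0.01. The remaining values were 0.66 for Il6, 0.17 for Nqo1, 0.11 for Mt1, 0.23 for Cdkn1a and 0.11 for Vegfa. The 5 panel calls fell to 0 without either saline array or either crocidolite array.

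Over all genes, limma called 0 of 22915 for crocidolite against saline (smallest adjusted p = 0.146), with 1670 under an unadjusted 0.05 (656 higher, 1014 lower, 1146 by chance). The count was 0 also with the replicate block (3065 unadjusted), a trended and robust prior (1631) and the 2 groups alone (1243). It was 2 with quantile normalization (smallest adjusted p = 0.00424) and 1, Hmox1, with the block and a trended and robust prior, a fit chosen after seeing the data. The smallest p belonged to Vmn2r109, Rbm46os, Catsperb, Rsph6a, Ttll7, Ereg, Ptgs2, Cd300ld4, Runx1 and Otx2. Runx1, a transcription factor of blood and mesenchymal cells, was higher by 2.17 ± 0.34 (4.50-fold, chromosome 16, 92605785 to 92605844), Ereg by 1.34 ± 0.20 and Ttll7, a tubulin glutamylase, by 0.92 ± 0.13. Otx2 stood at -0.97 ± 0.16 and Cd300ld4 at -1.22 ± 0.19. Under background with crocidolite were Vmn2r109 (at least 1.92-fold lower), Rbm46os (at least 2.26-fold), Catsperb (at least 2.88-fold) and Rsph6a (at least 1.51-fold), and Ptgs2 was under background in both groups. At 2-fold with no overlap, 180 genes were higher and 214 lower, and 34.4% of all genes had no overlap against 33.3% by chance. The calls numbered 47 without saline replicate 2 and 4 without either chrysotile array.

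Inflammatory, matrix protease and contractile lists were called upward with crocidolite too. TGF-beta, SRF and YAP targets had a median of 0.51 with 23 of 24 positive (camera adjusted p = 3.07e-10, 0.15 with an estimated correlation), with 1 of 24 past the threshold adjusted over the list alone and 14 with the replicate block. Ccn2, a matricellular protein, stood at 1.77 ± 0.92 and Ankrd1 at 1.45 ± 0.71 (above background on 1 of 2 saline arrays). Inflammatory cytokines and chemokines had a median of 0.81 with 17 of 23 positive (adjusted p = 2.23e-08, 0.15 with an estimated correlation), NF-kB genes 0.36 (5.65e-08, 0.15 with an estimated correlation) and matrix proteases 0.33 (2.56e-07, 0.16 with an estimated correlation). Acute phase and complement genes had a median of 0.67 (3.02e-07, 0.26 with an estimated correlation), adipokines 0.26 (2.9e-05, 0.26 with an estimated correlation) and growth factors 0.15 (0.000872, 0.15 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.24 with 27 of 28 positive (1.96e-08, 0.15 with an estimated correlation). Passing adjusted over the list alone, and chosen after their values were seen, were Ccl7 (1.29 ± 0.25), Ccl8 (2.22 ± 0.42), Ccl9 (2.57 ± 0.76, 5.94-fold), Cxcl1 (1.24 ± 0.41), Cxcl5 (1.27 ± 0.31), Cxcl12 (1.24 ± 0.40), Cx3cl1 (0.81 ± 0.19), Il33 (0.94 ± 0.31), Csf1 (0.68 ± 0.17), Ccl2 and Ptgs2. They make up 11 of 23 in the inflammatory list, with Ptgs2 under background in both groups, and Nos2, the inducible nitric oxide synthase, was the 1 lower (-0.51 ± 0.17). In the matrix list 6 of 23 passed, among them Mmp13 (2.07 ± 0.42, 4.19-fold), Mmp3 (1.56 ± 0.39), Plau (at least 2.16-fold, under background in saline), Plaur (0.94 ± 0.20, above background on 1 of 2 saline arrays) and Timp1 (0.99 ± 0.28, 0.059 with the replicate block). Vcam1 (0.85 ± 0.14), Nfkbie (0.86 ± 0.22) and Tlr2 (1.16 ± 0.28) passed in the NF-kB list, the last 2 not with the replicate block (0.051), and Bcl3 stood at 1.33 ± 0.38. Saa3, Lcn2, Serpina3g (2.64 ± 0.57) and C4b (2.46 ± 0.52) passed in the acute phase list (11 higher and 1 lower with the replicate block), where Hp, haptoglobin, stood at 3.53 ± 1.30. Ereg, Ccn5 (1.54 ± 0.38) in the adipokines, and the vasodilator peptide gene Adm (0.87 ± 0.18) and Ndrg1 (0.95 ± 0.19) in the hypoxia list (2 of 28, 6 with the replicate block) also passed, and Car9 stood at 1.45 ± 0.59. All of these lists but the growth factors, whose call ended without saline replicate 2 (adjusted p = 0.0783), held in the 15 other settings of the preset test.

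Other lists called for crocidolite were ER chaperones (median 0.25, 1.53e-05, 0.15 with an estimated correlation, Pdia3 0.51 ± 0.28, Calr 0.49 ± 0.16) and lysosome and phagosome genes (0.13, 7.04e-05, 0.24 with an estimated correlation, Scarb2 0.70 ± 0.19, Lgmn 0.58 ± 0.15), both upward. The integrated stress response rose (0.20, 0.000125, 0.31 with an estimated correlation, Gdf15 1.03 ± 0.56, Atf3 0.96 ± 1.05). The iron list also rose, by a median of 0.16 (0.0075, 0.16 with an estimated correlation), with the metalloreductase Steap4 at 1.68 ± 0.52. Upward too were heat shock genes (0.15, 0.0372, 0.46 with an estimated correlation), NRF2 antioxidant genes (0.08, 0.0452, 0.24 with an estimated correlation) and p53 targets (0.02, 0.0366, 0.26 with an estimated correlation, 0.0657 with the replicate block, Plk2 1.02 ± 0.17). The NRF2 and p53 medians lay at percentiles 91.37 and 62.45 of random lists of like brightness. Interferon genes rose by a median of 0.31 with 34 of 35 positive (2.58e-05, 0.49 with an estimated correlation), with pair medians of 0.71 and -0.09. Oxidative phosphorylation was the 1 list that fell, by a median of -0.25 with 30 of 30 negative (2.47e-07, 0.45 with an estimated correlation, Sdhb -0.46 ± 0.19, Uqcrc1 -0.44 ± 0.16). Adipocyte identity had a median of -0.16 (adjusted p = 0.0573, 0.00827 with the replicate block, Car3 -1.08 ± 0.66). Not called were lipogenesis at -0.05 (Thrsp -1.21 ± 0.36, Acacb -0.53 ± 0.18), cholesterol synthesis at 0.08 (Msmo1 0.30 ± 0.27), fatty acid oxidation at -0.13 (Cpt1a 0.48 ± 0.20), thermogenic genes at -0.18 (Cidea -0.79 ± 0.27), insulin signalling at -0.04 (Irs1 -0.49 ± 0.29). Nor were the metal response at 0.10 (Mt2 0.94 ± 0.26), the cell cycle at -0.08 (Cdc6 1.02 ± 0.21, Nusap1 -0.65 ± 0.20) or preadipocyte and fibroblast genes at 0.06 (S100a4 1.06 ± 0.41). The medians were 0.22 for macrophage markers (Mpeg1 0.99 ± 0.82), 0.02 for collagens and matrix (Col12a1 1.64 ± 0.33), 0.09 for autophagy (Gabarapl2 0.56 ± 0.40) and 0.07 for ribosomal proteins (Rpl5 0.35 ± 0.19). The circadian list had a median of -0.07, a mean of 0.01 and an upward test, and Hlf, a circadian transcription factor, passed adjusted over the list alone at -0.94 ± 0.17. Without saline replicate 2 the calls of oxidative phosphorylation, iron handling, the integrated stress response, heat shock, NRF2 and p53 targets ended (adjusted p 0.115 to 0.379). Without saline replicate 1 that of the interferon list ended (0.505, mean -0.10), without crocidolite replicate 1 those of the stress response, heat shock and p53 targets (0.103 to 0.474). Without a chrysotile array that of heat shock ended (0.0547), and the NRF2 call ended without any 1 of the 8 arrays (0.0529 to 0.167). With quantile normalization the NRF2, heat shock and p53 calls ended (0.116 to 0.292), with only probes bright on all arrays the NRF2 and heat shock calls (0.0502 and 0.0614), and with scaling on bright probes the NRF2 call (0.052).

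Amosite against saline gives the same measurement for the other amphibole, and the panel genes showed small values. Saa3 stood at 0.71 ± 1.01, Ccl2 at 0.62 ± 0.57, Spp1 at 0.39 ± 0.32 and Lcn2 at 0.23 ± 0.63, and 0 of 25 passed adjusted over the list alone (smallest adjusted p = 0.98). The adipocyte genes lay between -0.25 for Lep and 0.02 for Pparg, with Adipoq at -0.17, Retn -0.18, Cfd -0.16, Cebpa -0.02, Fabp4 -0.05, Plin1 -0.06, Slc2a4 -0.07, Fasn -0.18 and Scd1 -0.03. Stress, iron and growth factor genes gave 0.16 for Hmox1, 0.01 for Nqo1, -0.17 for Mt1, 0.12 for Tfrc, -0.05 for Cdkn1a, 0.02 for Ddit3, 0.00 for Hgf, 0.04 for Vegfa and -0.09 for Il6. Limma called 0 of 22915 genes (smallest adjusted p = 0.145), 610 had an unadjusted p under 0.05 (250 higher, 360 lower, 1146 by chance), and the count was 0 with the replicate block (1037 unadjusted), a trended and robust prior (381) and the 2 groups alone (503), and 2 with quantile normalization (smallest adjusted p = 0.00402). The smallest p belonged to genes lower with amosite. Bhlha9 stood at -1.70 ± 0.16, Timp3, an inhibitor of matrix proteases, at -1.34 ± 0.24 (amosite above background on 1 of 2 arrays), Mrgprb4 at -0.95 ± 0.18 and Krtap19-5 at -0.61 ± 0.11. Under background with amosite were Vmn2r109 (at least 1.87-fold lower), Rbm46os (2.2-fold), D1Ertd646e (2.08-fold), Slc26a9 (1.61-fold) and Atp12a (5.02-fold), each an at least value, and Oas3 was under background in both groups. At 2-fold with no overlap, 89 genes were higher and 79 lower, and 21.1% of all genes had no overlap. The chance share is 33.3% only if arrays are exchangeable, which same-numbered arrays were not. The calls numbered 59 without saline replicate 2 and 2 without either chrysotile array.

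Of the 31 lists, 3 were called for amosite. The interferon list fell, with a median of -0.21 and 33 of 35 negative (adjusted p = 0.0129, 0.98 with an estimated correlation), Rsad2 at -0.61 ± 0.24 and Mx1, an antiviral GTPase, at -0.54 ± 0.25; its pair medians were 0.02 and -0.48. Collagens and matrix fell, with a median of -0.15 and 27 of 29 negative (0.0129, 0.91 with an estimated correlation, Eln -0.51 ± 0.67, Col12a1 0.71 ± 0.33). Cell cycle genes rose by a median of 0.06 (0.0101, 0.98 with an estimated correlation), with the mitotic kinase Plk1 at 0.50 ± 0.16 and Mki67 at 0.47 ± 0.26. With the replicate block 6 lists passed, the others being NRF2 antioxidant genes (median 0.09, 0.0107, against 0.0991), adipocyte identity (-0.10, 0.0257, against 0.20) and the integrated stress response (0.04, 0.0448, against 0.197). Timp3 passed adjusted over the list alone in the matrix protease list (0.026, 0.058 with the replicate block), which had a median of 0.05. Among lists not called, the TGF-beta list stood at 0.02, NF-kB genes 0.07, acute phase genes 0.10, hypoxia genes 0.03, growth factors 0.01 (Ereg 0.79 ± 0.20, saline above background on 1 of 2 arrays), iron genes 0.07, lysosome genes 0.02, ER chaperones -0.07 and oxidative phosphorylation -0.07 (Cycs -0.31 ± 0.13). Fatty acid oxidation stood at 0.00, lipogenesis -0.03, thermogenic genes 0.03, insulin signalling -0.08, the metal response 0.00, heat shock 0.01, p53 targets 0.03, preadipocyte genes -0.04, autophagy 0.01, the circadian clock -0.06 and ribosomal proteins -0.04. Signs differed in 4 more: inflammatory cytokines had a median of -0.04, a mean of 0.02 and an upward test, and macrophage markers a median of 0.06, a mean of -0.01 and an upward test. Cholesterol synthesis had a median of 0.01 and a mean of -0.01, and adipokines a median of -0.03, a mean of 0.04 and a downward test. The interferon call ended without saline replicate 2 (adjusted p = 0.0585, mean 0.20) and amosite replicate 1 (0.852, mean -0.01), and the cell cycle call without saline replicate 1 (0.313) and amosite replicate 2 (0.234). The collagen call ended without either saline array or amosite replicate 1 (0.0931 to 0.545), and those of the interferon and collagen lists ended with normexp background correction (0.0991 and 0.156) and with no filter on dim probes (0.32). The collagen call also ended with quantile normalization (0.0689).

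**Figure D2:**
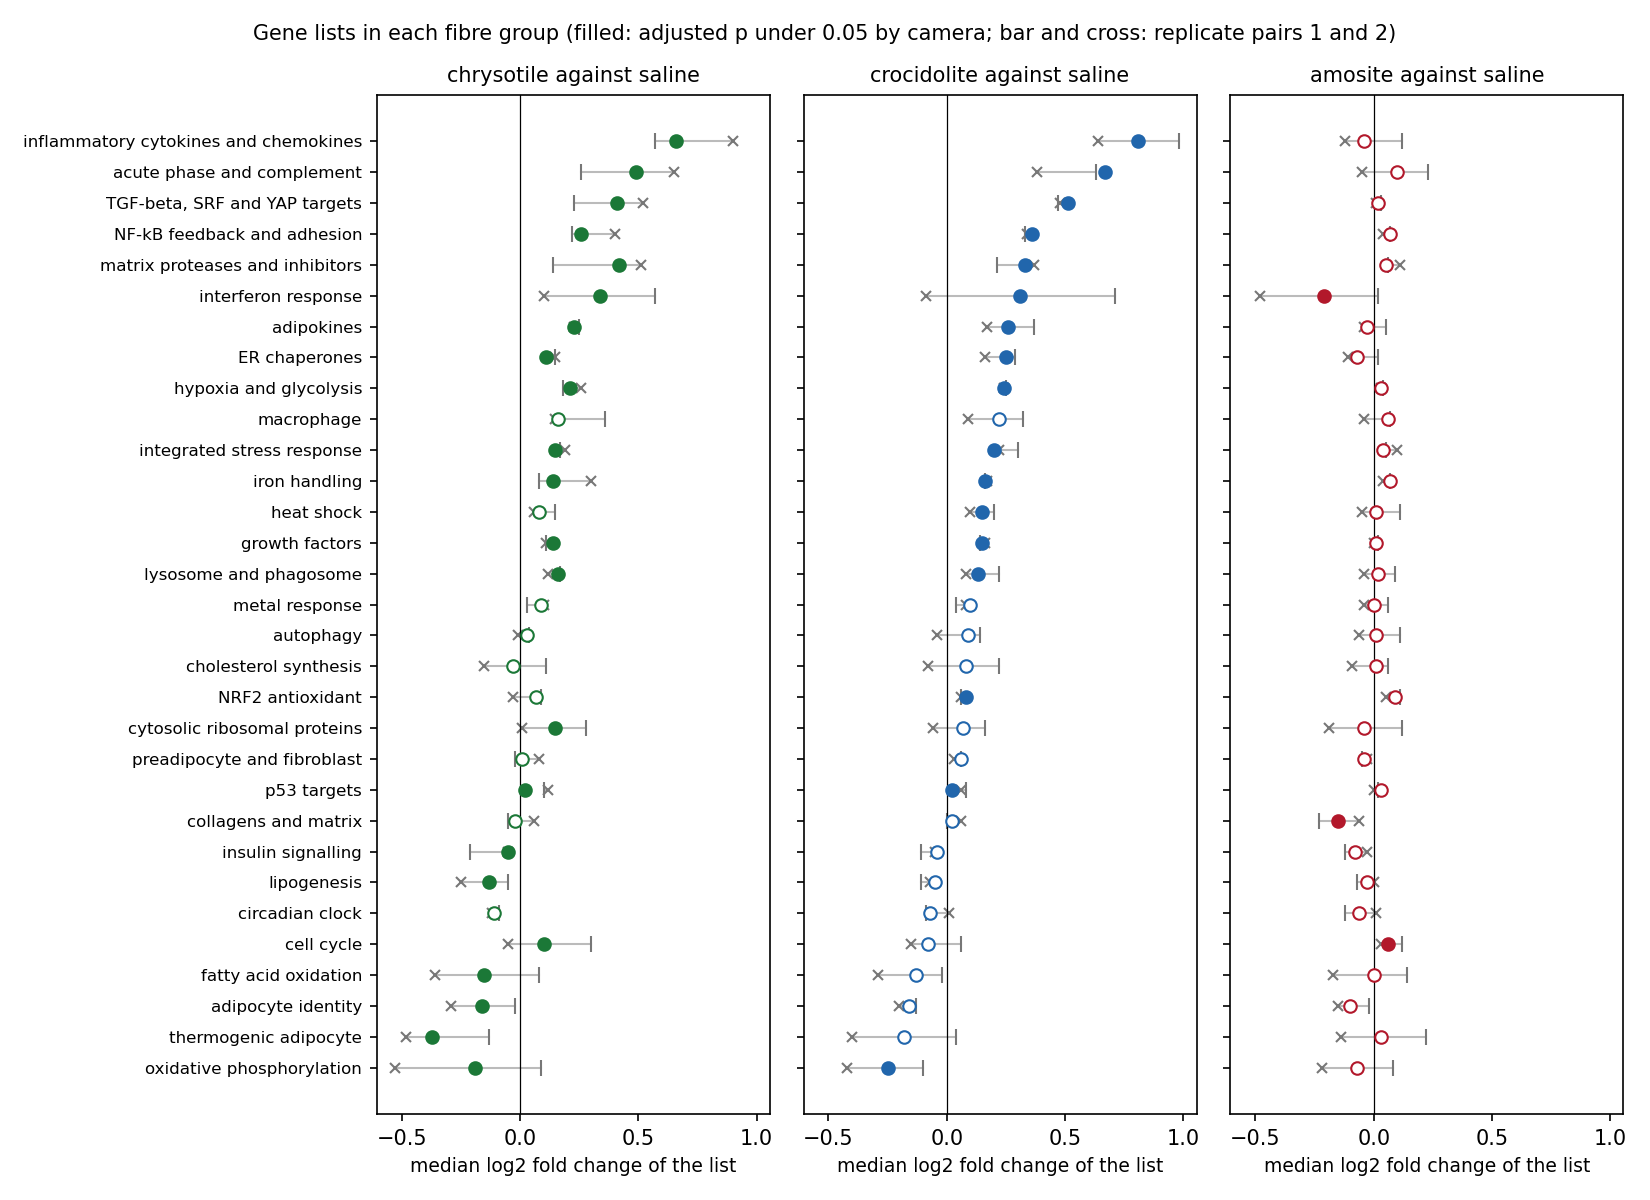
Median log2 fold change over the measured members of each of the 31 gene lists, for each fibre against saline, with filled points for lists past adjusted p 0.05 in the preset test and bars and crosses for replicate pairs 1 and 2. The largest median, 0.81, is that of the inflammatory list with crocidolite, which stands at 0.66 with chrysotile and -0.04 with amosite.

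Chrysotile was set against crocidolite to ask whether the serpentine and an amphibole fibre differ. For the inflammatory markers Ccl2 differed by 0.44 ± 0.57, Saa3 by -0.31 ± 1.01 (from -1.98 without chrysotile replicate 2 to 1.37 without chrysotile replicate 1), Lcn2 by -0.10 ± 0.63 and Spp1 by 0.59 ± 0.32. None of the 25 panel genes passed adjusted over the list alone (smallest adjusted p = 0.98). Limma called 0 of 22915 genes (smallest adjusted p = 0.866), with 634 under an unadjusted 0.05 (486 higher, 148 lower, 1146 by chance), and 0 with the replicate block (1037), a trended and robust prior (382) and the 2 groups alone (762). By p, Tnnt2 stood first, higher with chrysotile by 1.68 ± 0.21 (3.2-fold). Otx2 (1.00 ± 0.16) and Cd300ld4 (1.19 ± 0.19) were higher and Heatr7b1 lower (-1.90 ± 0.31). Under background with crocidolite and higher with chrysotile were Catsperb (at least 3.06-fold), Mtnr1b (at least 1.84-fold), Rsph6a (at least 1.41-fold), Olfr794 (at least 2.22-fold) and Tigit (at least 5.44-fold), and Vmn1r176 was at least 1.23-fold lower, with crocidolite above background on 1 of 2 arrays. At 2-fold with no overlap 182 genes were higher and 73 lower (23.3% with no overlap, 33.3% by chance). There was 1 call without chrysotile replicate 2.

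Between these fibres 6 lists were called. Cell cycle genes were higher with chrysotile, with a median of 0.12 and 29 of 33 positive (adjusted p = 0.0016, 0.79 with an estimated correlation, Nusap1 0.72 ± 0.20, Ccnb1 0.62 ± 0.31). Lower were cholesterol synthesis at -0.10 (0.00378, 0.79 with an estimated correlation, Srebf2 -0.34 ± 1.24), ER chaperones at -0.09 (0.0235, 0.79 with an estimated correlation, Dnajc3 -0.21 ± 0.12) and acute phase and complement at -0.19 (0.037, 0.85 with an estimated correlation, Hp -1.16 ± 1.30). So were the integrated stress response at -0.08 (0.037, 0.82 with an estimated correlation, Gdf15 -0.57 ± 0.56) and TGF-beta, SRF and YAP targets at -0.09 (0.037, 0.79 with an estimated correlation, Acta2 -0.42 ± 0.54). The pair medians of the acute phase list were -0.43 and 0.05, and those of the TGF-beta list -0.21 and 0.01. With the replicate block 10 passed, the others being collagens (0.0205), hypoxia (0.0325), the circadian clock (0.0228) and ribosomal proteins (0.021), with medians of -0.05, -0.04, -0.09 and 0.08. The remaining medians lay between -0.07 for NF-kB genes and 0.07 for matrix proteases (Mmp10 at least 1.81-fold higher, Plaur 0.54 ± 0.20). Signs differed for the interferon list (median 0.01, mean 0.02, downward test), p53 targets (mean 0.01, downward test) and macrophage markers (median -0.05, mean 0.02, upward test). Each call ended in some setting. Without chrysotile replicate 1 the acute phase list turned to a mean of 0.31 (adjusted p = 0.00338) and those of the TGF-beta, cholesterol, ER and cell cycle lists ended (0.0881 to 0.923). Without crocidolite replicate 1 the stress response, ER, cholesterol and TGF-beta calls ended (0.0503 to 0.672), and without chrysotile replicate 2 the stress response (0.603). Without crocidolite replicate 2 the cell cycle and acute phase calls ended (0.217 and 0.45), and without either saline array the acute phase, stress response and TGF-beta calls (0.0707). With quantile normalization all but the cell cycle call ended (0.0611 to 0.107), and with no filter on dim probes those of the acute phase and stress response (0.067).

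Chrysotile was set against amosite in the same way. With chrysotile, Ccl2 was higher by 2.38 ± 0.57 (5.22-fold) and Spp1 by 2.02 ± 0.32 (4.06-fold). These 2 were among the 3 of 25 panel genes that passed adjusted over the list alone (adjusted p = 0.044 and 0.016). With the replicate block 5 passed, with Saa3 (3.42, 0.04, against 0.07) and Hmox1 (1.16, 0.0061, against 0.71) added. Limma called 0 of 22915 genes (smallest adjusted p = 0.166), with 993 under an unadjusted 0.05 (603 higher, 390 lower, 1146 by chance), and 0 with the replicate block (1974), a trended and robust prior (946) and the 2 groups alone (1064). Normexp with the block, chosen after seeing the data, called 1, Tnnt2. By p, Tnnt2 (2.46 ± 0.21, 5.52-fold) stood first, then Oas3, an interferon-induced oligoadenylate synthase (at least 2.46-fold higher, under background with amosite). Bhlha9 (1.37 ± 0.16), Timp3 (1.75 ± 0.24, amosite above background on 1 of 2 arrays), Hmga2 (2.13 ± 0.31, 4.38-fold), Spsb4 (0.93 ± 0.14) and Acsbg1, an acyl-CoA synthetase (1.86 ± 0.29), were higher too. So were, under background with amosite, Prdm13 (at least 1.71-fold) and Tfpi2 (at least 1.42-fold, chrysotile above background on 1 of 2 arrays), and Vmn1r176 was at least 1.28-fold lower, under background with chrysotile. At 2-fold with no overlap 177 genes were higher and 89 lower (33.4% with no overlap, 33.3% by chance). Panel calls were 1 (Spp1) without either saline or either crocidolite array, 2 (Spp1 among them) without chrysotile replicate 2, 6 without chrysotile replicate 1 and 0 without either amosite array, and 1 gene was called over all genes without chrysotile replicate 2.

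The list test called 17 lists between chrysotile and amosite, 13 of them higher. Largest were the inflammatory list (median 0.66, 21 of 23 positive, adjusted p = 1.18e-11, 0.22 with an estimated correlation, Ccl8 1.95 ± 0.42) and the interferon list (0.50, 34 of 35 positive, 2.31e-11, 0.33 with an estimated correlation, Bst2 0.94 ± 0.73, Rtp4 0.93 ± 0.63), whose pair medians were 0.58 and 0.52. Matrix proteases (0.30, 2.06e-09), TGF-beta, SRF and YAP targets (0.38, 2.08e-07, Ccn2 1.70 ± 0.92), hypoxia genes (0.17, 1.72e-05, Car9 0.98 ± 0.59) and ER chaperones (0.17, 7.75e-05, Calr 0.59 ± 0.16) were higher, each with adjusted p = 0.22 with an estimated correlation. So were adipokines (0.16, 3.5e-07, 0.26 with an estimated correlation), acute phase genes (0.35, 1.72e-05, 0.31 with an estimated correlation), and ribosomal proteins (0.18, 1.93e-05, 0.55 with an estimated correlation). The ribosomal median lay at percentile 87.43 of random lists of like brightness, whose own median was 0.15. Also higher were NF-kB genes (0.21, 7.38e-05, 0.26 with an estimated correlation, Tlr2 1.12 ± 0.28), lysosome genes (0.15, 0.00275, 0.31 with an estimated correlation) and collagens (0.12, 0.024, 0.29 with an estimated correlation, Fbn1 0.61 ± 0.21). The collagen median lay at percentile 95.2 of random lists of like brightness. Growth factors were higher (0.13, 0.0312, 0.26 with an estimated correlation, 0.0694 with the replicate block, Inhba 1.02 ± 0.24). Lower were oxidative phosphorylation (-0.15, 1.72e-05, 0.55 with an estimated correlation, pair medians 0.00 and -0.31), and fatty acid oxidation (-0.19, 0.00211, 0.52 with an estimated correlation). Lower too were thermogenic genes (-0.29, 0.00409, 0.26 with an estimated correlation, Cidea -0.79 ± 0.27) and lipogenesis (-0.08, 0.0236, 0.59 with an estimated correlation, pair medians 0.05 and -0.17, Thrsp -0.94 ± 0.36). Those passing with the block alone were adipocyte identity (-0.06, 0.0343), iron handling (0.09, 0.0343) and macrophage markers (0.18, 0.0194). The calls of the inflammatory, interferon, matrix protease, TGF-beta, hypoxia and adipokine lists held in all 15 other settings. Without chrysotile replicate 2, 8 calls ended (fatty acid oxidation, oxidative phosphorylation, NF-kB, acute phase, ER, collagens, growth factors and lysosome, adjusted p 0.0668 to 0.544). Without amosite replicate 2 there were 4 (lipogenesis, thermogenic, growth factors and ribosomal, 0.0607 to 0.906). Without chrysotile replicate 1 there were 2 (lipogenesis and ribosomal, 0.238 and 0.239), without amosite replicate 1 there were 2 (collagens and lysosome, 0.053 and 0.266), and without a saline array growth factors ended (0.0688). That call also ended with no filter on dim probes (0.0704) and with only probes bright on all arrays (0.0817), and those of collagens, lysosome and ribosomal genes with quantile normalization (0.0675 to 0.24).

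Crocidolite was set against amosite to ask whether the 2 amphibole fibres differ. Spp1 was higher with crocidolite by 1.43 ± 0.32 (2.69-fold), and was among the 2 of 25 panel genes that passed adjusted over the list alone (adjusted p = 0.048). With the replicate block 6 passed, with Ccl2 (1.95, 0.022), Saa3 (3.72, 0.028), Hmox1 (1.42, 0.0023) and Tfrc (-1.01, 0.029) added. Limma called 0 of 22915 genes (smallest adjusted p = 0.224), with 1174 under an unadjusted 0.05 (568 higher, 606 lower, 1146 by chance), and 0 with the replicate block (2290), a trended and robust prior (1130) and the 2 groups alone (1817). By p, Oas3 stood first (at least 2.17-fold higher, under background with amosite). Runx1 (2.07 ± 0.34, 4.21-fold), Ttll7 (0.96 ± 0.13), Timp3 (1.37 ± 0.24, amosite above background on 1 of 2 arrays) and P2ry6, a nucleotide receptor (1.80 ± 0.31), were higher. So were, under background with amosite, Mtmr7 (at least 1.35-fold), Creb3l4 (at least 3.05-fold) and Tfpi2 (at least 1.2-fold). Mtnr1b (at least 1.6-fold) and Catsperb were lower, under background with crocidolite. For Catsperb the at least value equals the plain fold change of 2.4 (-1.26 ± 0.21). At 2-fold with no overlap 154 genes were higher and 175 lower (37.8% with no overlap, 33.3% by chance). The panel calls fell to 0 without any 1 saline, crocidolite or amosite array and numbered 6 without either chrysotile array.

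For crocidolite against amosite 19 lists were called, 16 of them higher. The TGF-beta, SRF and YAP targets (median 0.42, 23 of 24 positive, adjusted p = 3.18e-11, Ccn2 2.05 ± 0.92), the inflammatory list (0.75, 2.45e-10, Ccl9 2.15 ± 0.76), ER chaperones (0.27, 2.43e-08, Calr 0.66 ± 0.16), hypoxia genes (0.22, 2.43e-08, Ndrg1 0.99 ± 0.19) and growth factors (0.14, 0.00222, Inhba 1.08 ± 0.24) each had adjusted p = 0.13 with an estimated correlation. In the inflammatory list 10 of 23 were higher and 1 lower adjusted over the list alone. Interferon genes were higher by a median of 0.55 with 34 of 35 positive (3e-11, 0.34 with an estimated correlation, Oas2 0.91 ± 0.38), with pair medians of 0.74 and 0.35. Also higher were acute phase genes (0.59, 5.57e-09, 0.20 with an estimated correlation, Hp 3.37 ± 1.30), adipokines (0.31, 4.65e-07, 0.20 with an estimated correlation), and matrix proteases (0.23, 9.49e-07, 0.17 with an estimated correlation). So were NF-kB genes (0.29, 9.93e-07, 0.17 with an estimated correlation, Bcl3 1.27 ± 0.38), collagens (0.17, 0.000183, 0.15 with an estimated correlation, Col12a1 0.93 ± 0.33) and lysosome genes (0.12, 0.000293, 0.24 with an estimated correlation). The remaining calls were the integrated stress response (0.16, 0.00598, 0.43 with an estimated correlation), iron handling (0.16, 0.0146, 0.18 with an estimated correlation, Steap4 1.60 ± 0.52), ribosomal proteins (0.10, 0.0194, 0.64 with an estimated correlation) and heat shock genes (0.12, 0.0285, 0.43 with an estimated correlation). The ribosomal and heat shock medians lay at percentiles 63.92 and 96.19 of random lists of like brightness. Lower were oxidative phosphorylation (-0.20, 30 of 30 negative, 2.43e-06, 0.45 with an estimated correlation, Uqcrc1 -0.40 ± 0.16), with pair medians of -0.18 and -0.21, cell cycle genes (-0.13, 0.00542, 0.43 with an estimated correlation, Mki67 -0.70 ± 0.26) and fatty acid oxidation (-0.15, 0.0271, 0.57 with an estimated correlation). Macrophage markers (0.10, 0.0469) and thermogenic genes (-0.28, 0.0474) passed with the block alone, and insulin signalling had a median of 0.05, a mean of -0.01 and a downward test. The calls for 13 lists held in all 15 other settings. Those of fatty acid oxidation, the stress response, heat shock and ribosomal proteins ended without crocidolite replicate 1 (adjusted p 0.191 to 0.93). Those of iron and the cell cycle ended without crocidolite replicate 2 (0.055 and 0.225), and all 6 without amosite replicate 2 (0.0516 to 0.445, with a ribosomal mean of -0.04). That of fatty acid oxidation also ended with normexp (0.0852) and with no filter on dim probes (0.0576), and those of the stress response, heat shock and ribosomal proteins with quantile normalization (0.0756 to 0.885).

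Chrysotile was last compared with the mean of the 2 amphibole fibres. Tnnt2 was higher with the serpentine fibre by 2.07 ± 0.18 (4.2-fold), Hmga2 by 1.87 ± 0.27, Bhlha9 by 0.92 ± 0.14 and Spsb4 by 0.86 ± 0.12. Oas3 was among the 10 smallest p too, but it was above background on 2 of 4 amphibole arrays, so no value is given. Heatr7b1 stood at -1.74 ± 0.27, and Tigit and Epo, the erythropoietin gene, were above background with chrysotile and on none of the amphibole arrays. Vmn1r176 was under background with chrysotile and above it on 3 of 4 amphibole arrays, and Olfr297 stood at -0.89 ± 0.15, above background on 1 of 2 chrysotile arrays. Limma called 0 of 22915 genes (smallest adjusted p = 0.236), with 640 under an unadjusted 0.05 (428 higher, 212 lower, 1146 by chance), and 0 with the replicate block (1152) and a trended and robust prior (438). Normexp with the block, chosen after seeing the data, called Tnnt2 alone. At 2-fold from the amphibole mean, 87 genes were higher and 54 lower with no overlap between the chrysotile and crocidolite arrays. Overlap with the amosite arrays was not examined. Between chrysotile and crocidolite 23.3% of all genes had no overlap, where chance gives 33.3%. There was 1 call without chrysotile replicate 2.

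The responses to the fibres were compared with each other across genes, which are not independent replicates. The log2 fold changes of chrysotile and crocidolite against saline correlated with r = 0.70 and a covariance of 0.08, where 100 simulations of unchanged groups sharing the saline arrays gave 0.50 (highest 0.53) and 0.036 (highest 0.04). For chrysotile and amosite r was 0.51 with a covariance of 0.044, and for crocidolite and amosite 0.51 with 0.048. Both of these r lie within the simulated range, and all 3 covariances lie above the highest simulated one. With spreads from the fit with the replicate block the simulated covariance was 0.022. Chrysotile and crocidolite shared 675 genes under an unadjusted 0.05 in the same direction, 383 higher and 292 lower, where the simulations gave 42 and independence 18.5 and 27.1. Chrysotile and amosite shared 187 (82 higher, 105 lower, independence 7.1 and 9.6), and crocidolite and amosite 261 (55 higher, 206 lower, independence 7.2 and 15.9). Called over all genes, 0 were shared in any pair. The simulated r of 0.50 is that of groups with equal spread. Saline replicates differed most (SD of the difference 0.543, against 0.374 to 0.434 with the fibres), so the simulated values may be too low. The 2 saline arrays are too few to split. Part of the excess of chrysotile and crocidolite, and part or all of that of the pairs with amosite, may come from the shared saline arrays. In comparisons with no array in common, chosen after seeing the data, chrysotile minus saline and crocidolite minus amosite correlated with r = 0.35, and chrysotile minus amosite and crocidolite minus saline with 0.31. For the pairs with amosite the same comparisons have the sign turned by construction (-0.35 and -0.31). They therefore cannot show whether amosite shares a response. Leaving out 1 array gave r from 0.48 to 0.84, from 0.36 to 0.78 and from 0.42 to 0.77 for the 3 pairs.

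**Figure D3:**
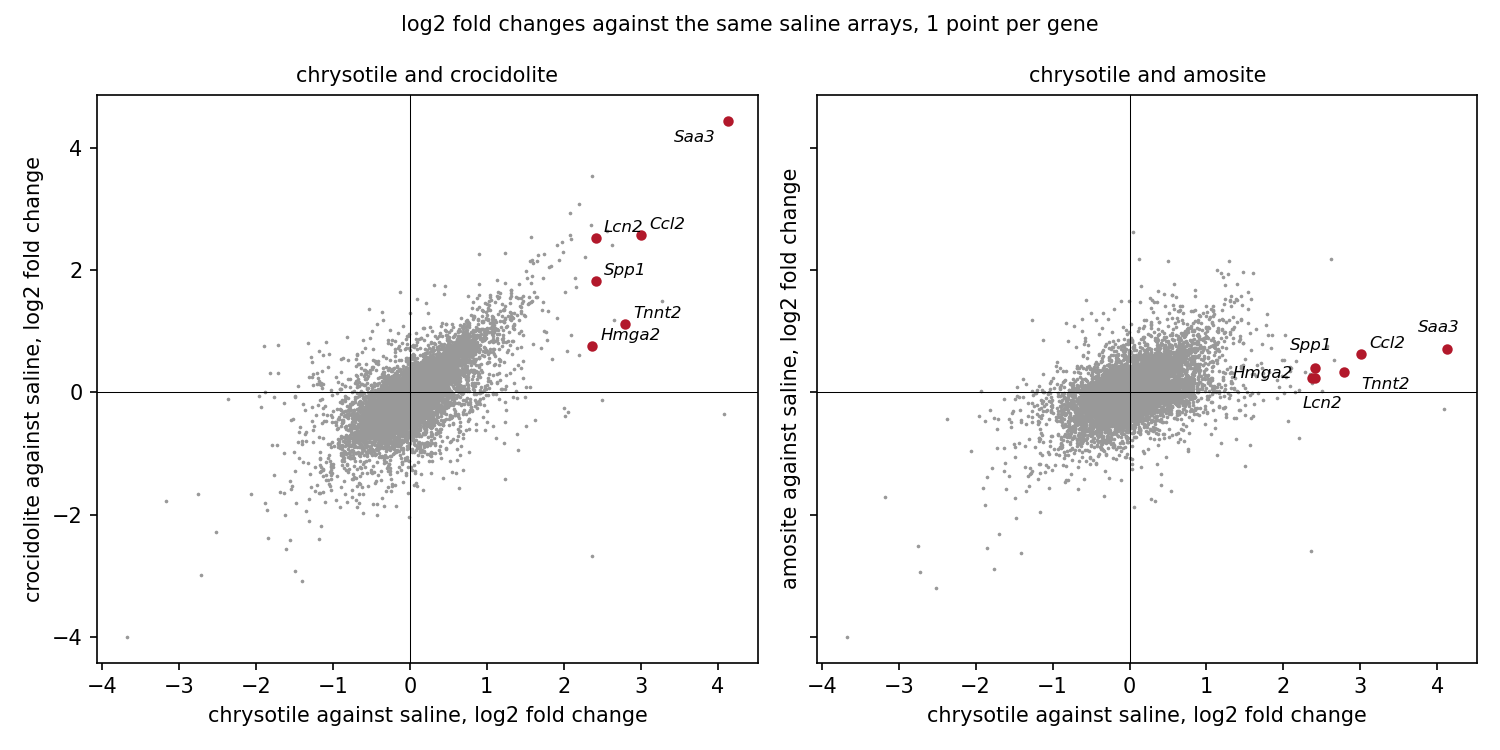
Log2 fold changes against saline of the 22915 genes tested, chrysotile on the x axes and crocidolite or amosite on the y axes, with 1 point per gene and 6 genes marked. Saa3 lies at 4.13 and 4.44 for chrysotile and crocidolite and at 0.71 for amosite.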

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

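The alternative settings chosen after the data were seen are the replicate block with a trended and robust prior and normexp with the block. Against saline, the gene counts of 0 became 3, 2 and 2 for chrysotile, crocidolite and amosite with quantile normalization (Tnnt2 with chrysotile, and Vmn2r109 and 1 transcript without a symbol in all 3). With the block and a trended and robust prior they were 6 for chrysotile and 1 for crocidolite, and with normexp and the block 2 for chrysotile, 1 for chrysotile against amosite and 1 for chrysotile against the amphiboles. The other planned settings kept 0. Leaving out 1 array gave 0 to 65, 0 to 47 and 0 to 59 calls against saline, 0 to 1 for chrysotile against crocidolite, amosite or the amphiboles, and 0 in each for crocidolite against amosite. Repeating the filter without the array let in probes bright on the lone array of that group (up to 24588 genes tested). Its counts are favoured by that choice and are not given. With the filter unchanged, many genes called without saline replicate 2 were the same for all 3 fibres, Mrpl1, Rnf130 and Kcne3 among them. All 3 comparisons then rest on saline replicate 1 alone, so such shared calls cannot be credited to a fibre. The cause of the calls gained without 1 array was not tested further.

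The replicate block moved the list counts to 6 for amosite and 10 for chrysotile against crocidolite, and the panel counts to 10 for crocidolite against saline, 5 for chrysotile against amosite (from 3) and 6 for crocidolite against amosite (from 2). Unadjusted gene counts rose, to 2416 from 1259 for chrysotile and to 3065 from 1670 for crocidolite, and members past the threshold adjusted over the list alone moved in many lists (TGF-beta targets from 0 to 10 with chrysotile and from 1 to 14 with crocidolite). With no other setting changed, the pairing changed no call over all genes, and of the lists and panel genes no other than those given with their blocked values in the results. Lists called fell from 22, 17, 3, 6, 17 and 19 to 0 in all 6 comparisons with an estimated correlation, to 0, 1, 0, 0, 0 and 0 in fry and 4, 10, 0, 0, 1 and 0 in its mixed form. For chrysotile against crocidolite normexp gave 11 and quantile normalization 1. Leaving out 1 array gave 12 to 22, 11 to 21, 1 to 7, 3 to 17, 13 to 18 and 15 to 25 lists. The panel counts became 3 for chrysotile with no filter and 8 for crocidolite with a trended and robust prior, with ranges of 0 to 6, 0 to 6 and 0 to 0 without 1 array. The correlation of chrysotile and crocidolite became 0.87 with normexp and 0.59 with no filter, and without 1 array the 3 ran from 0.48 to 0.84, 0.36 to 0.78 and 0.42 to 0.77. Signs reversed as follows, cause not tested beyond the left-out array. Adipocyte identity with chrysotile was 0.06 without saline replicate 2, in a range from -0.43. Interferon genes were -0.09 with chrysotile and -0.10 with crocidolite without saline replicate 1 (up to 0.74 and 0.72 without saline replicate 2), and with amosite 0.20 without saline replicate 2, with a test direction turned at -0.01 without amosite replicate 1 (lowest -0.63 without saline replicate 1). Between chrysotile and crocidolite, acute phase genes were 0.31 and TGF-beta targets -0.01 (test direction turned) without chrysotile replicate 1 (lowest -0.71 and -0.23 without chrysotile replicate 2), and the stress response 0.12 without crocidolite replicate 1 (lowest -0.32 without crocidolite replicate 2). Ribosomal genes were -0.04 for crocidolite against amosite without amosite replicate 2 (highest 0.23 without amosite replicate 1). Saa3 for chrysotile against crocidolite ran from -1.98 without chrysotile replicate 2 to 1.37 without chrysotile replicate 1. Signal over background limits Ptgs2, Plau, Oas3 and the other genes given as at least N-fold.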

Other observations

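The fits without 1 array, with the replicate block and with an estimated correlation were planned, and the tests of explanations below, including those that use these fits, were chosen after the result was seen. In the planned fit no gene was called over all genes, and 3 of those with the smallest p are described here as values. Tnnt2, which encodes a troponin, differed from saline by 2.79 with chrysotile, 1.11 with crocidolite and 0.33 with amosite, and Hmga2, which encodes a chromatin protein, by 2.37, 0.75 and 0.24. Runx1 stood 1.94 above saline with chrysotile, 2.17 with crocidolite and 0.10 with amosite. These genes were picked from the smallest p, so their sizes are likely overestimates. The fit with the replicate block and a trended and robust prior called 6 genes with chrysotile.

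The inflammatory, matrix protease and TGF-beta target lists were higher in chrysotile and crocidolite than in saline. A steady gradient along the slide, whose positions follow the groups, is argued against by the fall from crocidolite to amosite, the next position. The mean of the 3 lists differed by 0.53 in 1 slide column and 0.62 in the other. This does not test other effects of slide position: saline and amosite lay in the end rows, chrysotile and crocidolite in the middle rows. Such an effect cannot be told apart from the groups. A bias with brightness is argued against by random lists of like brightness, since all 6 medians lay at percentile 100 of 10000. As to a single aberrant or mislabelled array, 6 of 6 calls held without each of the 8 arrays in the preset test. None passed with an estimated correlation (adjusted p 0.15 to 0.22). The 3 lists are among those already seen to hold in every setting, so this outcome was fixed by their choice. It shows that no 1 array carries these calls, and is no separate test. A response to these 2 fibres may stand behind the pattern and remains a hypothesis, since amosite was given at the same stated amount and its fibre number was not measured here.

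Interferon genes were higher with chrysotile and crocidolite and lower with amosite in the preset test, and none of the 3 calls passed with an estimated correlation (adjusted p = 0.54, 0.49 and 0.98). The rise over saline may rest on saline replicate 1, whose list median was -0.53 relative to the mean of all arrays against 0.32 for saline replicate 2: without it the list means were -0.09 and -0.10. Saline replicate 1 was not the only low array, since amosite replicate 1 stood at -0.56 and amosite replicate 2 at -0.11. The fall with amosite had pair medians of 0.02 and -0.48, and its mean was 0.20 without saline replicate 2. Over amosite the list medians in the 2 slide columns were 0.58 and 0.52 for chrysotile and 0.74 and 0.35 for crocidolite, and both calls held in all 15 other settings of the preset test, the replicate block among them, but not with an estimated correlation (adjusted p = 0.33 and 0.34). Each group has 1 array of each number, so a number effect alike in all groups cannot make this difference, and one that varies between groups stays open, as does a difference between the fibres.

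Oxidative phosphorylation genes were lower with chrysotile and crocidolite in the preset test and did not pass with an estimated correlation (adjusted p = 0.54 and 0.45). Saline replicate 2 stood at 0.32 for this list and saline replicate 1 at -0.05, and without the former the adjusted p was 0.58 for chrysotile and 0.29 for crocidolite, so a high level on that array may account for the call against saline. Brightness is argued against, since both medians lay at percentile 0 of random lists. Fewer adipocytes among the cells cannot be told apart from a change within them: 5 abundant adipocyte genes stood 0.12 and 0.15 above the list, but the 2 columns gave 0 and 0.24 for chrysotile and 0.10 and 0.19 for crocidolite, and 2 columns are too few to exclude it. Against amosite, which does not use the saline arrays, the crocidolite call held in all 15 other settings of the preset test but not with an estimated correlation (adjusted p = 0.45), while that of chrysotile had pair medians of 0.00 and -0.31 and ended without chrysotile replicate 2 (adjusted p = 0.144), and a biological explanation was not tested.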
